A study of Mus musculus with 18 samples.

How the data were processed

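Poly-A RNA of 18 mouse placentas at embryonic day 12.5 was sequenced as stranded libraries, 1 placenta per library, after injection of the zygote with vehicle or let-7f-5p mimic. The deposited table holds, per the labels, 1 column of normalized signal per library, and the values show how they were made: in each column every value was a whole multiple of 1 step, so that the authors' values are rounded read counts divided by 1 size factor per library. Whole reads were recovered for 100% of values within 0.001 reads, with size factors from 0.383 to 1.59. Per the submitters' processing notes, the tools named were Trimmomatic 0.39, kallisto 0.50.1, DESeq2 1.48.2, FastQC 0.12.1 and MultiQC 1.28 with genome build GRCm39, without their order or settings. The filter on genes and the annotation release are not stated. The table had 17216 entries, of which 1 had no gene name and held 0.00582% to 0.0167% of a library's reads. It was left out. All columns belonged to the 18 samples.

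Library depth is the sum of recovered reads, 13.7 to 52.2 M reads (M, mega). For a count of 0, an upper limit of 3 reads was converted to normalized counts per library. This limit covers counting error only, since reads without molecular identifiers are not independent molecules.

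Values were tested as log2(normalized count + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend and robust). The 16518 genes with a mean of at least 10 normalized counts were tested, and 697 were left out. All libraries entered 1 model of 4 groups (treatment and sex) with 14 residual degrees of freedom and 6 contrasts: let-7f against vehicle as the mean of both sexes with equal weight, in males, in females, the female minus the male effect, and female against male within each treatment. P values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

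A set of 31 gene lists, for placental and maternal cell types, sex-linked and imprinted genes, let-7 targets and pathways, was tested with camera at a preset correlation of 0.01 and adjusted over the lists within a contrast. Camera with an estimated correlation, fry, which tests whether the genes of a list move on balance in 1 direction, and an exact permutation test of the library means of each list were run beside it. The permutation test ran within sex where both sexes entered, over 11760 splits, and over 56, 210, 126 and 84 splits for males, females, vehicle and let-7f. After adjustment over 31 lists, 1 list alone at the smallest p of these 4 would have an adjusted p of 0.554, 0.148, 0.246 and 0.369, so that it could not pass. In a list mean, each gene was centred over the libraries. Counts adjusted over the list alone used Benjamini-Hochberg within the list.

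Let-7 sites were searched in 3′ UTRs of GENCODE M21 (GRCm38), matched by gene name. This annotation is older than the build named by the submitters, so it was used for site presence and chromosome assignment only, and 96.3% of genes in the table had a chromosome and 89.3% a 3′ UTR. The site was CTACCTCA, from the mimic UGAGGUAGUAGAUUGUAUAGUU, and genes with it were compared with genes without the 6-base match TACCTC.

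Named genes were chosen per contrast: of genes past the threshold with a mean of at least 50 normalized counts in the higher group, the 12 largest rises and 12 largest falls; where fewer than 10 passed, the 10 with the smallest p; up to 4 members of each list with the smallest p; and a fixed set of sex-linked, let-7 target and growth genes. Gene models without a proper symbol were left unnamed where others filled the rule. Gm26992, Gm20431, Impdh2-ps and Wnt4 were named after their values were seen.

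Limma was tested in all 6 contrasts on simulated counts drawn from the real means and library sizes, with known genes changed. EdgeR and DESeq2 were tested for the mean of both sexes and for males. Camera and exact permutation were tested for the mean of both sexes, and fry was not tested. Each gene was drawn independently, so that the simulated libraries lack variation shared by many genes. Recovery and false calls in the real libraries can therefore differ from the values below. For the mean of both sexes, limma recovered 12.1%, 50.8% and 86.4% of genes changed 1.5-fold, 2-fold and 4-fold among 16388 genes. In males (16393 genes) it recovered 4.55%, 19.4% and 75.4%, and in females (16373 genes) 3.03%, 29.9% and 74.2%. For the difference between sexes (16373 genes) it recovered 0%, 2.99% and 37.9%, for vehicle females against males (16374 genes) 4.48%, 31.3% and 77.3%, and for let-7f females against males (16373 genes) 0%, 23.9% and 69.7%. For the mean of both sexes, DESeq2 recovered more, 27.3%, 62.7% and 93.9%, but called 38 unchanged genes, against 2 by edgeR and 3 by limma. The limma test of normalized values had been fixed as the main test beforehand, and DESeq2 stayed an alternative. Site genes lowered by 0.1 on the log2 scale among 16387 genes were recovered at -0.0985, and with nothing changed 0 genes were called in each of the 6 contrasts.

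Alternatives were pseudocounts of 0.5 and 10, no filter and a mean of at least 50, recomputed size factors, TMM scaling, quantile normalization, non-robust moderation, array quality weights, the replicate number as a block, list means of decidua, erythroid or yolk sac genes as covariates, a 7-base site and matched comparison genes for the let-7 sites, models of 2 groups only, an additive model, and each library left out in turn. Added after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, the 3 covariates together, exact permutation, and the omission of vehicle female 4 and let-7f female 6 together. Other tools were statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.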

Results

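Gene expression was measured by poly-A RNA sequencing in mouse placentas at embryonic day 12.5, after the zygote had received an injection of either nuclease-free water (the vehicle) or a synthetic mimic of the microRNA let-7f-5p. The 18 libraries each came from a separate placenta of an F1 cross. The 9 vehicle libraries came from 5 male and 4 female conceptuses, and the 9 let-7f libraries from 3 male and 6 female conceptuses. Nothing in the labels states which placentas shared a dam or a litter. Libraries held between 13.7 M reads (vehicle female 4) and 52.2 M reads (let-7f female 5), with a median of 35.9 M. The table listed 17215 named genes. A count of 0 allowed up to 1.88 normalized counts in the deepest library and up to 7.83 in the shallowest, for counting error only.

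The sex given for each placenta was checked first with transcripts of the Y chromosome. Eif2s3y, which encodes a Y-linked subunit of a translation initiation factor, was at 1356 ± 524 normalized counts in males (SD, n = 8) and at 1.77 ± 2.30 in females (n = 10), where no library held more than 5 reads of it. Ddx3y, a Y-linked RNA helicase gene, was at 474 ± 61.9 in males and 10.1 ± 9.83 in females, with at most 23 reads in a female library. Both genes put all 18 libraries on the side their labels gave. Kdm5d (753 ± 150 in males and 487 ± 247 in females) and Uty (114 ± 36.6 and 91.8 ± 67.4) had reads in female libraries as well and are uncertain, because each has a closely similar X-linked copy with which reads can be shared. The X-linked gene Ogt, whose product attaches O-GlcNAc to proteins and is known to be more abundant in female placenta, was at 1755 ± 169 in males and 3352 ± 973 in females. Xist was not in the table.

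**Figure D1:**
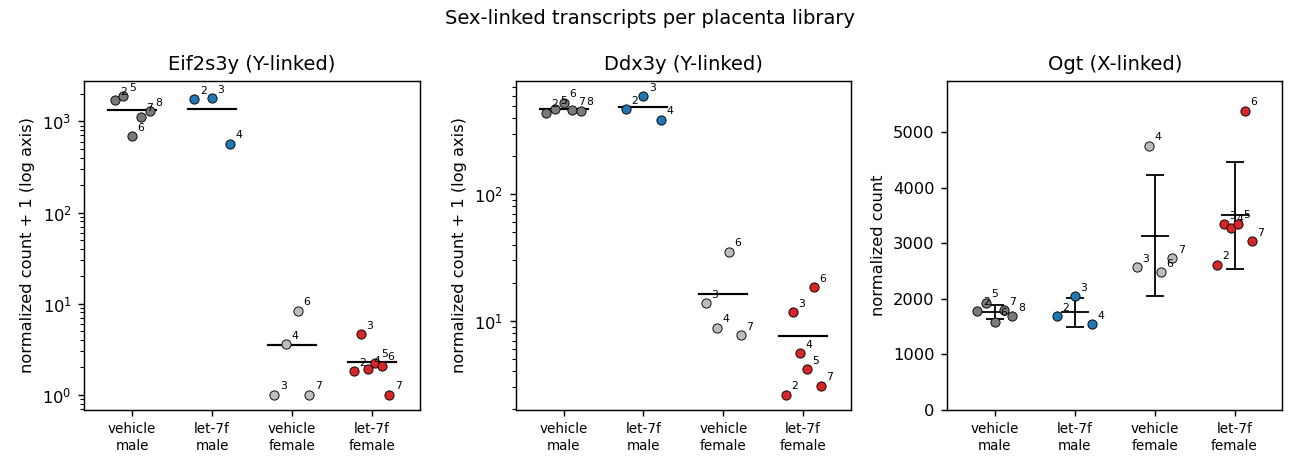
Normalized counts of Eif2s3y and Ddx3y (count + 1, log axis) and of Ogt (linear axis) in each of the 18 placentas, by treatment and sex. Points are libraries with their replicate numbers, horizontal lines are group means and the bars on Ogt are SDs; the 8 males and 10 females do not overlap for any of the 3 genes.

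Libraries also differed in the levels of genes listed as markers of single tissues. The lists of maternal decidual stroma and of uterine natural killer cells were both high on average in the same 4 placentas, let-7f female 3, let-7f male 2, vehicle female 6 and vehicle female 7. In these 4, the mean of the decidua list lay between 1.36 and 2.12 log2 units above the average of all libraries, and in the other 14 between -1.06 and 0.20. Gzmc, a granzyme gene of uterine natural killer cells, was at 20530 to 37320 normalized counts in the 4 and at 1008 to 2648 in the others. The 4 were picked as the highest on the list means, so that values of single members partly restate that choice. Of the 23 genes of both lists, 16 had these 4 as their 4 highest libraries. Others went against this, such as Bmp2, at 38.51 to 104.7 in the 4 and 33.64 to 122.6 in the others, and Wnt4, at 719.5 to 1403 and 224.3 to 1297. Let-7f female 6 stood apart on the second principal component, at -134. It had low list means for labyrinth trophoblast (-1.73), endothelium (-1.61), erythroid cells (-2.40) and yolk sac endoderm (-4.62). The yolk sac endoderm mean varied widely within groups, from -2.75 to 2.15 in vehicle males and from -4.62 to 1.49 in let-7f females. Vehicle female 4, the shallowest library, had 16.1% of its reads on Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, against at most 1.00% in any other library. This share is uncertain as a level of the gene, since reads resembling ribosomal RNA can be assigned to it and raw reads were not examined.

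**Figure D2:**
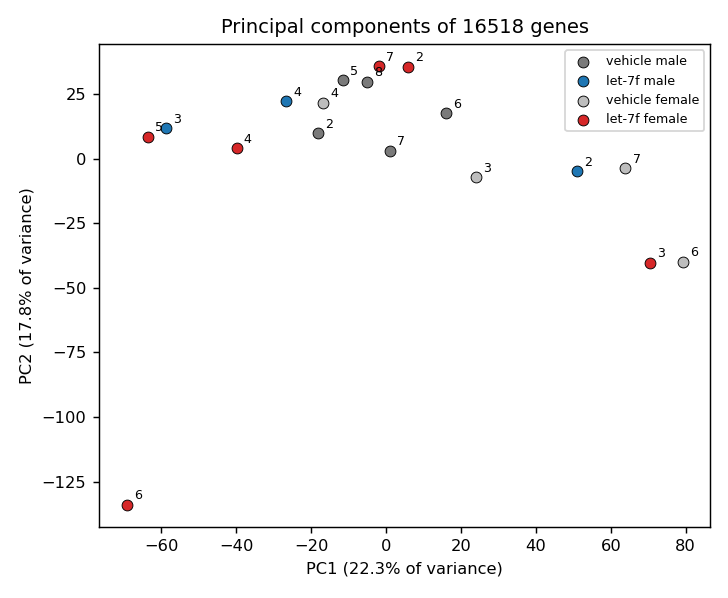
First and second principal components of the log2 values of 16518 genes, which held 22.3% and 17.8% of the variance; each point is 1 placenta, coloured by treatment and sex and marked with its replicate number. Let-7f female 6 lies at -134 on the second component, and neither component separates vehicle from let-7f libraries, although the 5 lowest on the first are let-7f libraries.

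The main comparison asked whether placentas that developed after zygotic let-7f differed from vehicle placentas, as the mean of the male and the female effect. The largest median shift among the 31 gene lists was in the junctional zone, the endocrine layer of the placenta that faces the decidua. Markers of spongiotrophoblast and glycogen trophoblast fell as a list after let-7f, with a median log2 fold change of -1.23 and 18 of 21 members lower (camera adjusted p = 6.44e-10; adjusted p = 0.494 with an estimated correlation). The mean of this list was 0.66 ± 0.28 in vehicle males (SD, n = 5), -0.78 ± 1.85 in let-7f males (n = 3), 0.40 ± 0.59 in vehicle females (n = 4) and -0.43 ± 0.96 in let-7f females (n = 6), on a log2 scale centred over all libraries. The fall was carried by 4 of the 9 let-7f libraries, male 3 (-2.87), female 5 (-1.96), female 4 (-0.96) and female 6 (-0.63). The other 5 lay between -0.13 and 0.68, within the range of the vehicle libraries (-0.34 to 1.07). Cell cycle genes rose as a list, with 30 of 30 members higher and a median log2 fold change of 0.35 (camera adjusted p = 6.44e-10, adjusted p = 0.661 with an estimated correlation). The list mean was highest in let-7f female 5 (0.90), male 3 (0.60), female 4 (0.41) and male 4 (0.40). The other let-7f libraries lay between -0.37 and 0.05, within the range of the vehicle libraries (-0.55 to 0.17). No single gene passed the test over all genes.

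Within the junctional zone list, 15 of 21 members had an unadjusted p under 0.05 and none passed, also when adjusted over the list alone. Log2 fold changes (± SE, here and below) were -2.85 ± 1.07 for the prolactin family gene Prl8a8, -1.84 ± 0.68 for the pregnancy-specific glycoprotein gene Psg23, -0.70 ± 0.25 for Aldh1a3, which makes retinoic acid, and -0.56 ± 0.21 for Pcdh12, a protocadherin gene of glycogen trophoblast. Of the cell cycle genes, Cdk1 was at 0.52 ± 0.20, the spindle gene Tpx2 at 0.52 ± 0.20 and the replication licensing genes Mcm3 and Mcm5 at 0.45 ± 0.18 and 0.52 ± 0.21. Trophoblast giant cell genes went both ways and were not called (median 0.21, 12 of 20 higher, adjusted p = 0.799). The placental lactogen gene Prl3d2 was at 2.69 ± 1.01, whereas the cathepsin genes Ctsq, Cts6 and Ctsm were at -1.34 ± 0.41, -2.67 ± 0.91 and -1.82 ± 0.70. These prolactin, glycoprotein and cathepsin genes belong to families of related genes, which can share reads to differing degrees. Such sharing was not tested, so that their single values are uncertain.

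Genes of metabolism and hormone synthesis made up the rest of the lists that rose. The hypoxia list rose by a median of 0.18 (17 of 25 higher, camera adjusted p = 0.00446; adjusted p = 0.494 with an estimated correlation), and its leading members were glycolytic genes, with Aldoa at 0.40 ± 0.09, Ldha at 0.42 ± 0.12 and Pgk1 at 0.36 ± 0.11. Aldoa, the muscle-type aldolase gene, was at 14658 ± 1750 normalized counts in vehicle males, 19747 ± 2773 in let-7f males, 14168 ± 590.2 in vehicle females and 18545 ± 2251 in let-7f females (SD). Adjusted over the list alone, 3 hypoxia genes passed upward. Steroid hormone synthesis genes rose by a median of 0.44 (9 of 11 higher, camera adjusted p = 0.00409; adjusted p = 0.494 with an estimated correlation). They included Cyp11a1 (1.25 ± 0.49), which makes pregnenolone from cholesterol, Star (1.44 ± 0.66), which moves cholesterol into mitochondria, and Cyp17a1 (0.64 ± 0.23). The list mean was highest in the same 4 let-7f libraries that were lowest for the junctional zone list, at 0.509 to 1.197 against at most 0.20 in the other 14. Cholesterol synthesis genes rose by 0.12 (16 of 19 higher, camera adjusted p = 0.00327, adjusted p = 0.661 with an estimated correlation), with Dhcr7 at 0.72 ± 0.29 and Idi1 at 0.46 ± 0.18. The mean of this list went from -0.113 in vehicle to 0.208 in let-7f males, but only from -0.010 to -0.004 in females. Respiratory chain genes of mitochondrial DNA rose by 0.33 (11 of 12 higher, camera adjusted p = 0.00908, adjusted p = 0.661 with an estimated correlation), with mt-Nd1 at 0.70 ± 0.35. Their list mean went from -0.271 in vehicle to 0.460 in let-7f females, where the SD was 1.15, but only from -0.217 to -0.197 in males.

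The lists that fell, besides the junctional zone, were those of vessels, blood, immune cells and matrix. Interferon-stimulated genes fell by a median of -0.32 (26 of 29 lower, camera adjusted p = 0.000447), endothelial genes by -0.40 (16 of 18, 0.00327), erythroid genes by -0.47 (17 of 22, 0.00359), macrophage genes by -0.36 (16 of 17, 0.00908) and matrix genes by -0.14 (21 of 25, 0.0308). Each of these 5 had an adjusted p = 0.661 with an estimated correlation. The antiviral gene Rsad2 was at -0.57 ± 0.15 and was the 1 interferon gene that passed when adjusted over the list alone, whereas Mx1 was at 1.59 ± 0.54. The alpha globin gene Hba-a2 was at -1.73 ± 0.62, the endothelial sialomucin gene Emcn at -0.55 ± 0.31, the macrophage lysozyme gene Lyz2 at -1.65 ± 0.64 and the elastin gene Eln at -1.16 ± 0.43. Erythroid and endothelial means were lowest in let-7f female 6 (-2.40 and -1.61) and let-7f male 4 (-2.49 and -0.93). Interferon and macrophage means were lowest in let-7f male 3 (-0.86 and -1.11) and let-7f female 5 (-0.83 and -0.70).

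**Figure D3:**
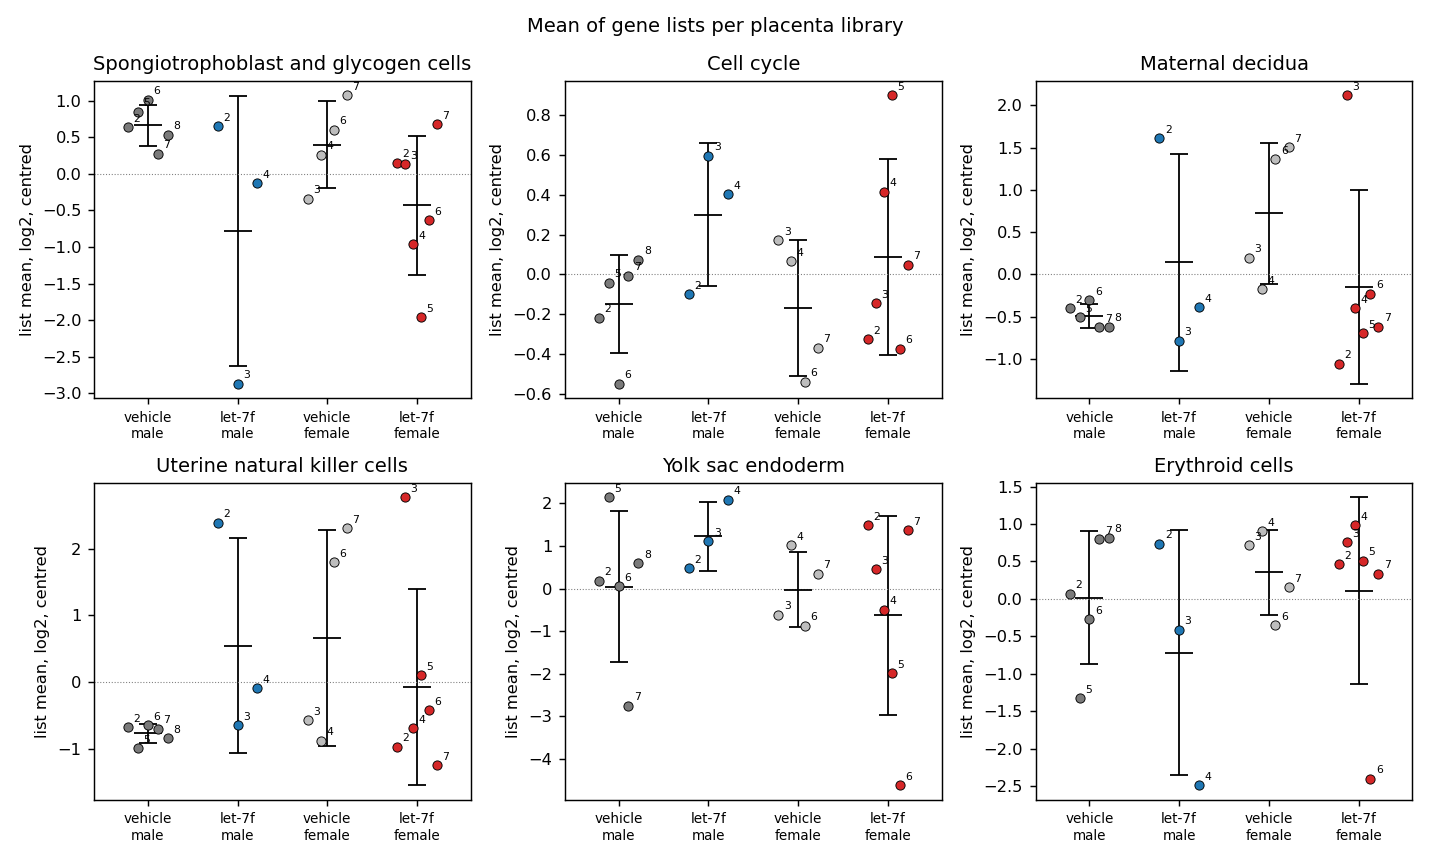
Mean log2 value of 6 gene lists in each placenta, centred over the 18 libraries; points are libraries with replicate numbers, and bars are the mean and SD of each group. The spongiotrophoblast and glycogen cell list reaches -2.87 in let-7f male 3, and the decidua and uterine natural killer lists are high in the same 4 libraries of 3 groups.

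Several genes outside these lists had the smallest p values of the comparison, all with adjusted p = 0.655. They included Phgdh at 0.88 ± 0.22, the entry enzyme of serine synthesis, Smc1a at 0.47 ± 0.12, a cohesin gene, Synpo at 0.76 ± 0.19, an actin-binding protein gene, Izumo1r at -2.01 ± 0.44, the egg receptor for sperm IZUMO1, and Gpx2 at -1.76 ± 0.45, a glutathione peroxidase. Stress and amino acid response genes were not called as a list (10 of 20 higher, adjusted p = 0.121), but 3 of them passed upward when adjusted over the list alone, led by Phgdh, Psat1 (0.84 ± 0.26) and Asns (0.46 ± 0.13). Igf2, the imprinted growth factor gene, was at 32633 ± 9847 normalized counts in vehicle males, 13391 ± 7625 in let-7f males, 22461 ± 9178 in vehicle females and 15817 ± 9119 in let-7f females, a log2 fold change of -0.999 ± 0.33. Pappa2, which encodes a protease that frees insulin-like growth factors from binding proteins, was at -1.19 ± 0.48 and Igfbp7 at -0.86 ± 0.27, and the insulin-like growth factor list was not called (11 of 19 lower, adjusted p = 0.38).

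The remaining lists did not pass, with adjusted p of 0.0655 for let-7 targets, 0.119 for epigenetic regulators, 0.166 for yolk sac endoderm, 0.232 for nutrient transporters, and 0.251 for X-linked escape genes, smooth muscle and labyrinth trophoblast alike. Y-linked genes and uterine natural killer genes were at 0.316, embryo tissue genes at 0.38, decidua genes at 0.503, imprinted genes at 0.604 and glucocorticoid genes at 0.636. Nuclear respiratory chain genes and neutrophil genes were at 0.891, immediate early genes at 0.96 and ribosomal protein genes at 0.987. For the nuclear respiratory chain list the camera test pointed up while the median was -0.03.

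By limma, 0 of 16518 genes had an adjusted p under 0.05, the lowest being 0.655. Of all genes, 1241 (7.51%) had an unadjusted p under 0.05, of which 592 were higher and 649 lower after let-7f. With nothing changed, a share of 0.05 of genes would lie there on average. On reads recovered from the table, the edgeR quasi-likelihood test called 0 genes and DESeq2 called 12. Of the 31 lists, camera with its preset correlation called 11, and none was called with an estimated correlation, by fry, or by an exact permutation test of library means, where the junctional zone list had the lowest unadjusted p (0.0138 over 11760 splits, adjusted p = 0.427). Several list calls ended without 1 library, where brackets hold, here and below, the median and the adjusted p without it. Without let-7f male 3, the junctional zone median was -0.57 and still called, while interferon (-0.14, 0.145), macrophage (-0.17, 0.202), steroid (0.32, 0.0511), mitochondrial (0.19, 0.127) and matrix genes (0.01, 0.744) were no longer called. Without let-7f male 4, endothelial (-0.23, 0.178) and erythroid genes (-0.07, 0.592) were not called. Without let-7f female 6, erythroid (-0.14, 0.0984), mitochondrial (0.22, 0.105) and matrix genes (-0.04, 0.306) were not. The matrix call also ended without vehicle male 5 (-0.12, 0.0701), vehicle female 4 (-0.07, 0.168) or vehicle female 7 (-0.15, 0.0659). The cholesterol median was 0.07 without let-7f female 5 and the hypoxia median 0.10 without vehicle female 3, both still called. Still called, with medians moved by over 1.5 times, were erythroid (-0.86), hypoxia (0.11), macrophage (-0.58) and mitochondrial (0.57) genes without let-7f male 2. So were matrix (-0.25) genes without let-7f female 3 as well as endothelial (-0.22) genes without let-7f female 6. This also held for cholesterol (0.08) genes without let-7f male 3 as well as matrix (-0.30) genes without let-7f male 4. Nor did the call end for matrix (-0.25) genes without vehicle female 3. Fold changes were computed on log2(value + 1), which understates those of genes with low counts.

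Because the series is about sex-specific growth, the effect was then estimated in each sex. In male placentas the junctional zone list fell by a median log2 fold change of -1.67 (19 of 21 lower, camera adjusted p = 7.3e-12; adjusted p = 0.314 with an estimated correlation). Tpbpa, the classical spongiotrophoblast marker, was at 495280 ± 103000 normalized counts in 5 vehicle males and 265460 ± 221600 in 3 let-7f males (-1.67 ± 0.72), Psg17 at -2.30 ± 0.96, Prl8a9 at -1.42 ± 0.64 and Pcdh12 at -0.76 ± 0.32. Cell cycle genes rose, 30 of 30 being higher (median 0.45, camera adjusted p = 3.42e-11; adjusted p = 0.586 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, at 1.07 ± 0.50 and the proliferation marker Mki67 at 0.48 ± 0.27. All 19 cholesterol synthesis genes were higher (median 0.27, camera adjusted p = 2.62e-07; adjusted p = 0.311 with an estimated correlation), among them Cyp51 at 0.46 ± 0.19 and Idi1 at 0.62 ± 0.28.

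Genes of yolk sac endoderm rose by a median of 1.29 (20 of 21 higher, camera adjusted p = 7.2e-06, adjusted p = 0.586 with an estimated correlation). The retinol carrier gene Rbp4 was at 2.00 ± 1.17 and Soat2, which esterifies cholesterol, at 1.27 ± 0.58. The list means of the let-7f males (0.48 to 2.09) lay within the range of the vehicle males, from -2.75 (vehicle male 7) to 2.15. Hypoxia genes rose by 0.20 (camera adjusted p = 0.000799; adjusted p = 0.311 with an estimated correlation), with the prolyl hydroxylase gene Egln3 at 1.45 ± 0.45. For the lists that follow, the brackets hold the median, the camera adjusted p and the adjusted p with an estimated correlation. Uterine natural killer genes (1.54, 0.00061, 0.586) and decidua genes (0.52, 0.0148, 0.586) rose with the high values of let-7f male 2. Erythroid genes (-0.69, 7.36e-05, 0.586) and endothelial genes (-0.46, 0.00107, 0.586) fell with the low values of let-7f male 4. Interferon genes fell (-0.23, 0.00149, 0.586), as did matrix (-0.10, 0.0191, 0.59), trophoblast giant cell (-0.22, 0.0297, 0.586), macrophage (-0.28, 0.0491, 0.59) and immediate early genes (-0.31, 0.0491, 0.586). Let-7 target genes (0.16, 0.00787, 0.586), ribosomal protein genes (0.09, 0.00681, 0.729) and glucocorticoid genes (0.20, 0.028, 0.586) rose.

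Among single genes, none of which passed in males, Ghrh, the gene of growth hormone-releasing hormone, was at 16676 ± 4020 normalized counts in vehicle and 7436 ± 1730 in let-7f males (-1.16 ± 0.31). Hmga2, a chromatin gene and textbook let-7 target, was at 82.6 ± 26.1 and 211 ± 66.2 (1.36 ± 0.38). Igf2 was at -1.36 ± 0.49 and Igf2r, which clears its product, at -0.82 ± 0.41. Adjusted over the list of insulin-like growth factor genes alone, Igfbp3 (1.07 ± 0.33) and Igfbp7 (-1.34 ± 0.40) passed in opposite directions. The serine synthesis genes Psat1 and Phgdh were at 1.16 ± 0.38 and 0.92 ± 0.33. The ion channel genes Hcn3 and Kcnb1 were at 2.91 ± 0.70 and -2.12 ± 0.57, the milk fat gene Btn1a1 at -2.13 ± 0.56, and the fatty acid carrier gene Cd36 at -1.43 ± 0.58. The placental lactogen gene Prl3b1 was at -0.95 ± 0.37.

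By limma 0 genes passed in males, with a lowest adjusted p of 0.9997. An unadjusted p under 0.05 was found for 443 genes (165 higher, 278 lower). These are 2.68% of the genes tested, fewer than the share of 0.05 that chance gives on average. EdgeR called 0 genes, DESeq2 called 1 with all libraries and 19 with the 8 male libraries alone, and limma called 1, the pseudogene Impdh2-ps, without vehicle male 7. Exact permutation called 0 lists, a count that says little, since with 56 splits the smallest p is 0.0179 and 12 lists would have to reach it for any to pass. With 3 let-7f males, single libraries set the size of many values. Without let-7f male 3, the junctional zone median was -0.37 (adjusted p = 0.0276) and the cell cycle median 0.29, both still called. The ribosomal median turned to -0.07 (0.0138), and the calls ended for interferon (0.02, 0.624), let-7 target (-0.03, 0.762) and matrix genes (0.25, 0.499). Without let-7f male 2 they ended for uterine natural killer (0.48, 0.397), decidua (-0.14, 0.54) and glucocorticoid genes (0.10, 0.547), the hypoxia median was 0.04 and that of cell cycle genes 0.70. Without let-7f male 4 they ended for erythroid (0.12, 0.812) and endothelial genes (-0.19, 0.812). Of the vehicle males, number 5 ended the matrix (0.02, 0.0769) and ribosomal calls (0.06, 0.194), numbers 2 and 8 the ribosomal call (0.05, 0.157 and 0.05, 0.138). Numbers 7 and 8 ended the glucocorticoid call, at medians no smaller than with all libraries (0.21, 0.0592 and 0.23, 0.0778), and the yolk sac median was 0.57 without number 7. The trophoblast giant cell, macrophage and immediate early calls ended in 5, 10 and 14 of the 18 refits without 1 library, in 3, 2 and 1 of which the median moved by over 1.5 times, with adjusted p of up to 0.135, 0.762 and 0.762. The giant cell median was 0.03 without let-7f male 4, and the macrophage and immediate early medians -0.06 and 0.02 without let-7f male 3. Still called, with medians moved by over 1.5 times, were endothelial (-0.75), erythroid (-1.36), matrix (-0.27), interferon (-0.47), let-7 target (0.29), macrophage (-0.52) and ribosomal (0.14) genes without let-7f male 2. So were matrix (-0.53), glucocorticoid (0.31), hypoxia (0.11), interferon (-0.41), macrophage (-0.48) and ribosomal (0.23) genes without let-7f male 4 as well as decidua (0.93) and glucocorticoid (0.48) genes without let-7f male 3. This also held for matrix (-0.24) and ribosomal (0.19) genes without vehicle male 6 as well as matrix (-0.17) and ribosomal (0.15) genes without vehicle male 7. Nor did the call end for matrix (-0.05) and giant cell (-0.35) genes without vehicle male 8.

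In female placentas, the lists called included a fall of decidua and junctional zone genes and a rise of cell cycle genes and of respiratory chain genes encoded in mitochondrial DNA. Decidua genes were lower in all 14 members (median log2 fold change -0.88, camera adjusted p = 0.00268; adjusted p = 0.807 with an estimated correlation), with the progesterone receptor gene Pgr at -2.11 ± 1.23 and the gap junction gene Gja1 at -1.19 ± 0.74. Of the 4 libraries high for this list, 2 were vehicle females. Mitochondrially encoded genes were higher in all 12 (median 0.76, camera adjusted p = 0.00229; adjusted p = 0.807 with an estimated correlation), with mt-Cytb at 1.17 ± 0.45 and mt-Co1 at 0.95 ± 0.37. Let-7f female 6 had the highest share of such reads, 1.82%. Junctional zone genes fell by a median of -0.81 (19 of 21 lower, camera adjusted p = 0.00268; adjusted p = 0.807 with an estimated correlation), with Ascl2, the transcription factor gene needed for spongiotrophoblast, at -0.83 ± 0.40 and Psg23 at -1.68 ± 0.91. Cell cycle genes rose by 0.26 (27 of 30 higher, camera adjusted p = 0.00229; adjusted p = 0.807 with an estimated correlation), with Tpx2 at 0.61 ± 0.26 and Cdk1 at 0.58 ± 0.26.

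Steroid synthesis genes rose in let-7f females by a median of 0.52 (9 of 11 higher, camera adjusted p = 0.0133; adjusted p = 0.807 with an estimated correlation), with Star at 1.86 ± 0.88 and Hsd17b2, which inactivates estradiol, at 0.63 ± 0.28. Trophoblast giant cell genes rose by 0.44 (16 of 20 higher, camera adjusted p = 0.0339; adjusted p = 0.807 with an estimated correlation). Among them were the proliferin gene Prl2c3 at 1.68 ± 0.68, Prl7d1 at 0.78 ± 0.32 and the placental lactogen genes Prl3d1 and Prl3d2 at 2.41 ± 1.19 and 3.08 ± 1.33. Interferon genes (median -0.29, camera adjusted p = 0.0151), macrophage genes (-0.43, 0.0489) and ribosomal protein genes (-0.12, 0.0339) fell, with adjusted p of 0.807, 0.807 and 0.866 with an estimated correlation.

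Single genes with the smallest p in females included Btg3, an antiproliferative gene, at 0.89 ± 0.18, Golga5 at 0.68 ± 0.17, Izumo1r at -2.45 ± 0.58 and the vomeronasal receptor gene Vmn2r93 at -1.69 ± 0.40. Each had adjusted p = 0.622. Ndufs1, a core subunit of respiratory complex I, was at 1157 ± 226 normalized counts in vehicle and 1849 ± 393 in let-7f females (0.67 ± 0.16). It was the 1 nuclear respiratory chain gene that passed when adjusted over its list alone. Tmed2b had 0 reads in all 4 vehicle female libraries, which allows up to 7.83 normalized counts in the shallowest of them, against 113 ± 145 in let-7f females and 54.5 ± 34.4 in vehicle males (SD). Its name marks it as a copy of Tmed2, with which reads can be shared, so that these values are uncertain. Phgdh was at 0.85 ± 0.29, the unfolded protein response gene Xbp1 at 0.52 ± 0.17, the glucocorticoid-induced gene Zbtb16 at -1.06 ± 0.33, Hmga2 at 0.50 ± 0.33 and Igf2 at -0.64 ± 0.43.

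By limma 0 genes passed in females, and 1216 (7.36%) had an unadjusted p under 0.05 (730 higher, 486 lower). EdgeR called 0 genes, DESeq2 12 with all libraries and 11 with the 10 female libraries alone, and limma called 2 without let-7f female 3 (Tmed2b and Gm20431). Exact permutation called 0 lists, where 3 would have to reach the smallest p of 210 splits, 0.00476, for any to pass at it. Camera called 9 lists, 1 without vehicle female 7 and 12 without vehicle female 4. Without vehicle female 7 the calls ended, at medians moved by less than 1.5 times, for junctional zone (-0.63, 0.0658), decidua (-0.63, 0.0658), cell cycle (0.19, 0.0546), steroid (0.45, 0.0546) and interferon genes (-0.22, 0.141). Without let-7f female 6 they ended for mitochondrial (0.44, 0.0888), trophoblast giant cell (0.11, 0.377), steroid (0.39, 0.0775) and interferon genes (-0.24, 0.0775). The cell cycle call also ended without vehicle female 6 (0.15, 0.0689) or let-7f female 5 (0.09, 0.167), and the interferon call without let-7f female 5 (-0.19, 0.199). The trophoblast giant cell call ended without vehicle female 3 (0.32, 0.0683), 4 (0.32, 0.146), 7 (0.46, 0.0546) or let-7f male 3 (0.44, 0.0593). The macrophage and ribosomal calls ended in 8 and 6 of 18 refits, in 1 and 2 of which the median moved by over 1.5 times, with adjusted p of up to 0.167 and 0.432, and the ribosomal median was 0.02 without vehicle female 3. The decidua median was -1.42 without let-7f female 3 and -0.54 without vehicle female 6, and the junctional zone median -0.50 without let-7f female 5, each still called. Still called, with medians moved by over 1.5 times, were decidua (-1.34), macrophage (-0.67) and ribosomal (-0.30) genes without vehicle female 4. So were giant cell (0.77) genes without let-7f female 2 as well as macrophage (-0.71) genes without let-7f female 3.

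Whether the effect of let-7f differed between the sexes was tested directly as female minus male. Trophoblast giant cell genes had a higher effect in females (median log2 difference 0.76, 18 of 20 positive, camera adjusted p = 0.000194; adjusted p = 0.579 with an estimated correlation). The cathepsin gene Ctsj was at 0.83 ± 0.36, Prl7d1 at 1.09 ± 0.49 and Prl3b1 at 1.05 ± 0.49. Yolk sac endoderm (median -2.02, camera adjusted p = 6.24e-06; adjusted p = 0.964 with an estimated correlation), decidua (-1.30, 6.24e-06) and uterine natural killer genes (-2.51, 0.000217) had a lower effect in females. The last 2 lists are those that were high in 2 vehicle females, 1 let-7f male and 1 let-7f female, and had an adjusted p of 0.579 with an estimated correlation. Of single genes, Igfbp3 was at -1.46 ± 0.44, Zbtb16, which passed when adjusted over the glucocorticoid list alone, at -1.75 ± 0.50, Ndufs1 at 0.87 ± 0.25, the calcium channel gene Cacnb4 at 1.96 ± 0.49, Rrm2 at -1.54 ± 0.67 and Hmga2 at -0.86 ± 0.50.

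Cholesterol synthesis (median -0.25, camera adjusted p = 0.000525), ribosomal protein (-0.21, 6.24e-05) and glucocorticoid genes (-0.36, 0.0134) also had a lower effect in females, and immediate early (0.45, 0.00728), mitochondrial (0.70, 0.0108) and junctional zone genes (0.64, 0.0369) a higher one. With an estimated correlation, none of these 10 lists had an adjusted p below 0.579, and exact permutation called 0. By limma 0 genes passed, with a lowest adjusted p of 0.998. An unadjusted p under 0.05 was found for 391 genes (2.37%), fewer than the share of 0.05 that chance gives on average. EdgeR called 0 genes and DESeq2 6, and limma called 1, Tmed2b, without let-7f female 3. The junctional zone difference was -0.61 without let-7f male 3 and lost its call in 8 of 18 refits, in 2 of which the median moved by over 1.5 times. Single libraries also ended the calls for cholesterol (let-7f male 3, -0.13, 0.0932), glucocorticoid (let-7f male 2, -0.34, 0.185, its size hardly moved), ribosomal (let-7f male 3, -0.04, 0.882; vehicle female 3, -0.07, 0.464) and immediate early genes (let-7f male 3, 0.29, 0.189; vehicle female 3, 0.31, 0.0885). The mitochondrial call ended without let-7f female 6 (median 0.35, 0.256), let-7f female 3 (0.69, 0.0645) or let-7f male 2 (0.45, 0.243). Without let-7f male 2 the decidua and uterine natural killer medians were -0.58 and -1.45, both still called, as was the yolk sac median of -1.17 without let-7f female 6. Still called, with medians moved by over 1.5 times, were junctional zone (1.08) genes without let-7f female 5. So were junctional zone (1.4798) genes without let-7f male 2 as well as ribosomal (-0.32) genes without let-7f male 4. This also held for ribosomal (-0.38) genes without vehicle female 4 as well as junctional zone (0.98) genes without vehicle female 7. Nor did the call end for yolk sac (-1.27) genes without vehicle male 7. Across 16518 genes, which are not independent replicates, the male and female effects had a Pearson correlation of 0.116 and a Spearman correlation of 0.176, and 57.9% of genes had the same sign. The effects share no library, and 57 of 100 splits of the samples within sex gave a correlation as far from 0 (permutation p = 0.57), with values from -0.08 without let-7f male 3 to 0.33 without let-7f male 2.

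Genes known as let-7 targets were examined because the injected RNA was a let-7 mimic. They were not lower after let-7f: 22 of 32 tested targets were higher, with a median log2 fold change of 0.09 (camera adjusted p = 0.0655). In the reference used, 18 of the 32 held the 8-base let-7 site in a 3′ UTR and 24 a 7-base site. Only embryonic day 12.5 was measured, so that these values do not tell whether targets were lower sooner after the injection. Hmga2 was at 82.6 ± 26.1 normalized counts in vehicle males, 211 ± 66.2 in let-7f males, 103 ± 38.2 in vehicle females and 149.9 ± 61.7 in let-7f females, a log2 fold change of 0.93 ± 0.25 over both sexes (adjusted p = 0.655). Hmga1, a related chromatin gene, was at 0.51 ± 0.21 and the cell cycle phosphatase gene Cdc25a at 0.42 ± 0.19, and neither held the 8-base site. Lin28b, which blocks let-7 maturation, was at -0.10 ± 0.36, and the RNA-binding protein genes Igf2bp1, Igf2bp2 and Igf2bp3 at 0.37 ± 0.20, 0.35 ± 0.22 and -0.05 ± 0.16. None of the 32 passed when adjusted over the list alone.

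**Figure D4:**
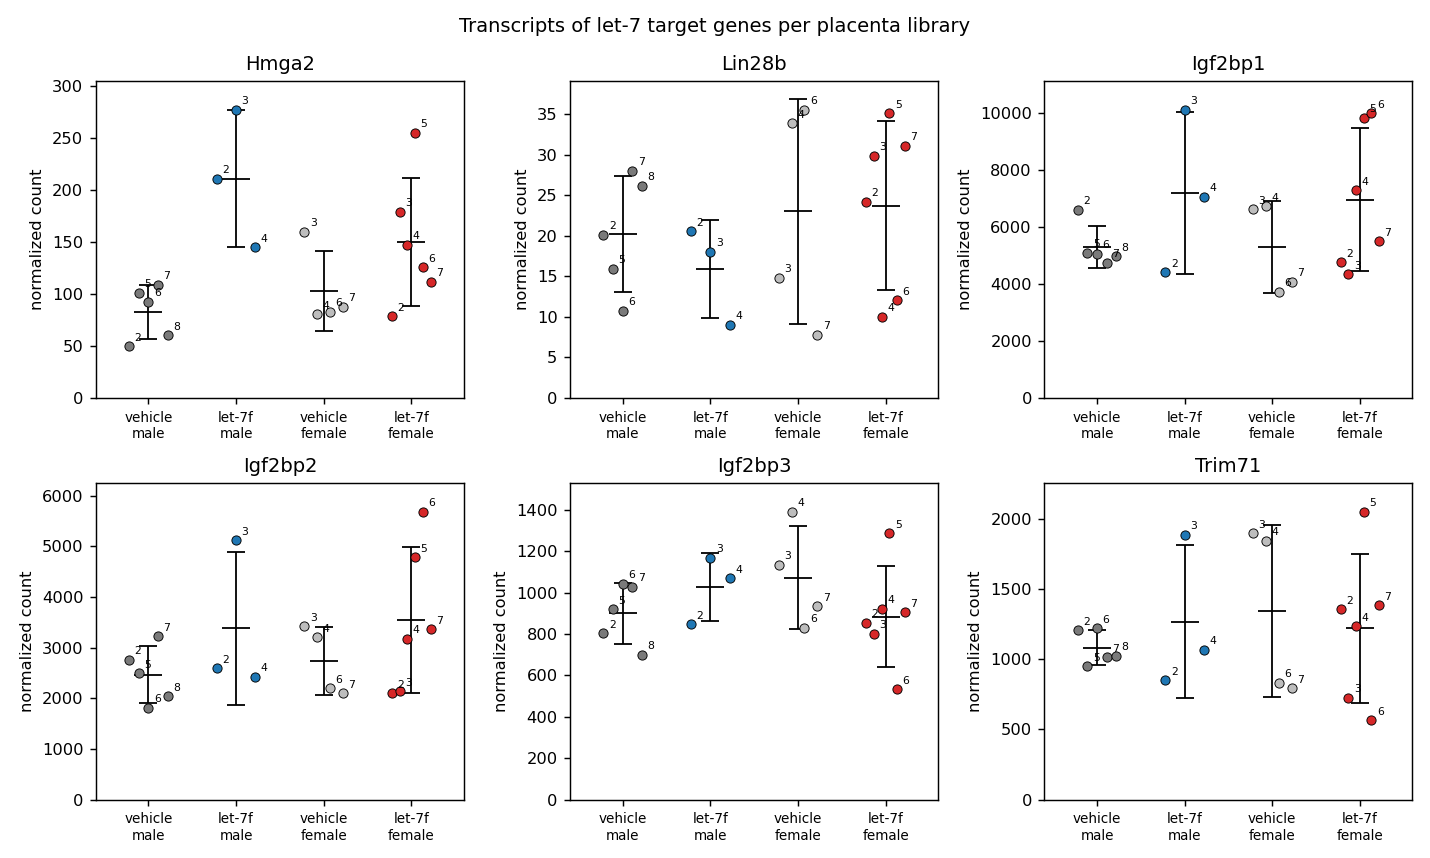
Normalized counts of 6 let-7 target genes in each placenta, by treatment and sex; points are libraries with replicate numbers, and bars are the mean and SD of each group. Hmga2 lies between 145 and 277 in the 3 let-7f males and between 49.8 and 109 in the 5 vehicle males, and Lin28b is at most 35.5 in any library.

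Transcripts were also grouped by whether their annotated 3′ UTR holds the let-7 site CTACCTCA, the match to the seed of the mimic. Of the tested genes, 14944 (90.5%) had a 3′ UTR in the reference, 579 held the 8-base site and 10817 held no 6-base match. The median log2 fold change of site genes differed from that of genes without a match by -0.0069 as the mean of both sexes, 0.011 in males and -0.0053 in females, and by 0.011 for the difference between the sexes. Against 579 genes matched on 3′ UTR length and expression the 4 differences were 0.0097, 0.0135, 0.0426 and 0.0582, so that the sign turned for the mean of both sexes and for females. For the 1677 genes with a 7-base site they were -0.0139, -0.0018, -0.019 and -0.0059, with the sign turned for males and for the difference. Exact permutation tests used the difference of mean log2 values in each library, which was 0.0077, 0.0231, -0.0076 and -0.0307 and thus opposite in sign to the medians for the mean of both sexes and the difference. They gave two-sided p = 0.838, 0.464, 0.938 and 0.682, and with matched genes 0.176, 0.643, 0.205 and 0.466 (exact permutation). Camera gave an adjusted p of 0.832 for each of the 4 and pointed down for the difference, while the medians pointed up.

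Female and male placentas were compared within each treatment, first among vehicle placentas (4 females, 5 males). Eif2s3y (log2 fold change -9.08 ± 0.60, adjusted p = 2.16e-07) and Ddx3y (-5.12 ± 0.53, 0.000122) fell in females, and the X-linked gene model Gm26992 rose from 2.19 ± 2.76 to 94.8 ± 102 normalized counts (0.0157). Genes of decidua were higher in females in 13 of 14 members (median 1.31, camera adjusted p = 2.73e-06; adjusted p = 0.56 with an estimated correlation), with Pgr at 2.88, the homeobox gene Hoxa10 at 1.85 ± 0.82 and Gja1 at 1.75 ± 0.77. Vehicle females 6 and 7 were 2 of the 4 libraries high for this list. Uterine natural killer genes rose with them (median 1.73, 0.00138; adjusted p = 0.869 with an estimated correlation), including Gzmc at 2.24 ± 1.06 and the perforin gene Prf1 at 1.73 ± 0.89. Glucocorticoid-induced genes rose by 0.37 (12 of 14 higher, 0.00138; adjusted p = 0.56 with an estimated correlation); Zbtb16, at 36.9 ± 2.36 in males and 105 ± 29.6 in females (1.45 ± 0.35), passed when adjusted over that list alone. The glucocorticoid list mean was highest in the same 4 libraries that were high for decidua, among them vehicle females 6 and 7 (0.62 and 0.44), and was at -0.04 and 0.04 in vehicle females 3 and 4.

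X-linked escape genes rose in vehicle females (median 0.37, camera adjusted p = 0.0105; adjusted p = 0.56 with an estimated correlation), led by Ogt at 0.78 ± 0.20, which passed when adjusted over the list alone. Y-linked genes fell (-2.97, 1.11e-10; adjusted p = 0.000824 with an estimated correlation). Trophoblast giant cell genes fell by -0.45 (18 of 20 lower, 0.0236; adjusted p = 0.977 with an estimated correlation), with Ctsj at -0.56 ± 0.24 and Prl3b1 at -0.46 ± 0.34. Ribosomal protein genes rose by 0.15 (0.00151; adjusted p = 0.977 with an estimated correlation). By limma 3 of 16518 genes passed (1 higher, 2 lower), of which 1 was on X among 599 tested X-linked genes. An unadjusted p under 0.05 was found for 889 genes (5.38%), close to the share of 0.05 that chance gives on average. EdgeR called 2 genes, DESeq2 16, and DESeq2 on the vehicle libraries alone 425. The call of Gm26992 ended without vehicle male 6 (adjusted p = 0.0641), 7 (0.0651) or 8 (0.068), or vehicle female 4 (0.0731), 6 (0.0599) or 7 (0.0525). The Y-linked, decidua and glucocorticoid lists all had the smallest p that 126 splits can give (exact permutation p = 0.00794, adjusted p = 0.082), so that this test did not call even the Y-linked list here. Without vehicle female 4 the X-linked median was 0.14 (0.401) and the giant cell call ended (-0.38, 0.169). The giant cell call also ended without vehicle female 3 (-0.41, 0.0734), vehicle male 2 (-0.31, 0.0859) or 6 (-0.40, 0.0672), and the X-linked call without vehicle male 6 (0.29, 0.0684). The natural killer call ended without vehicle female 7 (1.16, 0.104). The ribosomal call ended without vehicle female 3 (0.01, 0.886), vehicle male 2 (0.10, 0.0655) or 5 (0.09, 0.0698). Still called, with medians moved by over 1.5 times, were glucocorticoid (0.57) genes without vehicle female 3. So were ribosomal (0.32) genes without vehicle female 4 as well as X-linked (0.24) genes without vehicle male 7.

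Among let-7f placentas (6 females, 3 males), Eif2s3y (-9.21 ± 0.63, adjusted p = 4.07e-07) and Ddx3y (-6.35 ± 0.55, 1.01e-05) fell in females. Yolk sac endoderm genes fell by a median of -2.04 (20 of 21 lower, camera adjusted p = 7.56e-16, adjusted p = 0.554 with an estimated correlation). Rbp4 was at -2.33 ± 1.13, Soat2 at -1.39 ± 0.56 and Mttp, which loads lipid onto lipoproteins, at -1.05 ± 0.53. The list mean ranged from -4.62 (let-7f female 6) to 1.49 in let-7f females and from 0.48 to 2.09 in let-7f males, so that the groups overlapped. Erythroid genes rose by 0.90 (21 of 22 higher, 1.11e-07; adjusted p = 0.626 with an estimated correlation), with Hbb-bs at 1.07 ± 0.61 and Alas2, the first enzyme of erythroid haem synthesis, at 1.12 ± 0.70. Trophoblast giant cell genes rose by 0.49 (17 of 20 higher, 0.00393; adjusted p = 0.626 with an estimated correlation), with Prl2c3 at 1.05 ± 0.74 and Prl3b1 at 0.60 ± 0.36. X-linked escape genes rose by 0.37 (3.37e-06; adjusted p = 0.103 with an estimated correlation), with Eif2s3x at 0.52 ± 0.22. Ogt, at 0.96 ± 0.21, did not pass over all genes (adjusted p = 0.893) but passed when adjusted over the list alone. Y-linked genes fell (-3.65, 4.78e-22; adjusted p = 1.36e-05 with an estimated correlation).

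Cholesterol synthesis genes fell in let-7f females against let-7f males (median -0.19, all 19 lower, camera adjusted p = 0.000176; adjusted p = 0.554 with an estimated correlation), as did cell cycle genes (-0.20, 0.000507; 0.926 with an estimated correlation) and ribosomal protein genes (-0.09, 0.0253; 0.949). Mitochondrially encoded genes rose (0.48, 0.000176; 0.626 with an estimated correlation), as did endothelial (0.16, 0.00915; 0.894) and immediate early genes (0.25, 0.0119; 0.626). By limma 2 genes passed, both lower. An unadjusted p under 0.05 was found for 193 genes (1.17%), fewer than the share of 0.05 that chance gives on average. EdgeR called 2 genes, DESeq2 4 and DESeq2 on the let-7f libraries alone 5. Ogt was called (0.83, adjusted p = 0.0248) when vehicle female 4 and let-7f female 6 were both left out, a choice made after the data were seen. Without let-7f male 4 the erythroid median was 0.02 (0.99) and the endothelial median -0.13 (0.703). Without let-7f male 3 the ribosomal median was 0.09 and the calls ended for cell cycle (-0.07, 0.819), cholesterol (-0.10, 0.336) and immediate early genes (0.05, 0.688). Without let-7f female 6 they ended for giant cell (0.16, 0.599), mitochondrial (0.12, 0.19), immediate early (0.14, 0.162) and ribosomal genes (-0.05, 0.162). The yolk sac median was then -1.15, still called. The mitochondrial call also ended without let-7f male 2 (0.23, 0.245), the cell cycle call without let-7f female 2 (-0.12, 0.0787) and the ribosomal call without let-7f female 4 (-0.08, 0.206). The endothelial call ended without let-7f female 2 (0.17, 0.0721), 3 (0.13, 0.079), 4 (0.13, 0.116) or 5 (0.13, 0.0566). Still called, with medians moved by over 1.5 times, were endothelial (0.37), erythroid (1.61), immediate early (0.40), cell cycle (-0.43) and ribosomal (-0.15) genes without let-7f male 2. So were endothelial (0.54), erythroid (1.39) and cell cycle (-0.13) genes without let-7f female 6 as well as immediate early (0.40) and cell cycle (-0.36) genes without let-7f female 5. This also held for endothelial (0.25) and mitochondrial (0.73) genes without let-7f male 3 as well as ribosomal (-0.23) genes without let-7f male 4.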

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

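The tests of tissue content, depth and handling on the 4 libraries high for maternal genes and on let-7f female 6 were chosen after the result was seen, as was the test of spread without 2 libraries, and the other tests of spread and the counts of splits before.

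The decidua and uterine natural killer lists were high in the same 4 libraries, let-7f female 3, let-7f male 2, vehicle female 6 and vehicle female 7. Let-7f female 3 was far from the other let-7f females at 2.116 and 2.774, against -0.23 and 0.10 in the next library. Prl8a2, a prolactin family gene of decidua, was at 49720 to 142400 normalized counts in the 4 and 4645 to 56700 in the others, and Gzmd at 21970 to 68110 against 1878 to 5152. The 14 and 9 members tested share no gene with another list. Treatment as the whole cause is argued against by 2 vehicle libraries among the 4, and sex as the whole cause by 1 male among them. Maternal tissue left on some placentas and a difference of decidual invasion in these conceptuses both stay open. The overlap of the 4 highest libraries for each list, 4, restates the pattern and decides nothing. The same holds in part for the ranges of single members, since the 4 were picked on the list means. How each placenta was separated from decidua is not stated.

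Let-7f female 6 lay far from the other let-7f females, where the values that follow are list means with the nearest other library in brackets. It was at -1.73 (-0.06) for labyrinth trophoblast, -1.614 (0.10) for endothelium, -2.399 (0.33) for erythroid cells, -2.021 (-0.13) for smooth muscle, -1.105 (-0.12) for imprinted genes, 1.723 (0.16) for trophoblast giant cells and 0.7449 (0.16) for immediate early genes, and its Ogt was at 12.39 (11.71) on the log2 scale. Shallow sequencing is argued against by its 36.9 M reads, within the range of its group. The lists of labyrinth, vessels, blood and matrix, 4 of 4, were lowest of the 6 let-7f females, and those of immediate early and mitochondrial genes, 2 of 2, were highest of the 18. Most of these lists are among those that set the library apart, so that these counts decide nothing. A piece with little labyrinth and RNA quality or handling stay open, as does a let-7f effect in this 1 conceptus, which no group of the design can test.

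The let-7f libraries spread wider around their group means than the vehicle libraries, with a ratio of mean squared distances of 1.51. Chance is not excluded by the exact permutation test (two-sided p = 0.164 over 11760 splits). Without let-7f female 6 the ratio was 1.23 (exact permutation p = 0.318, 7056 splits), and with the decidua list mean removed it was 1.3 (exact permutation p = 0.628). Without both vehicle female 4 and let-7f female 6 it was 1.47 (exact permutation p = 0.0724, 3136 splits), close to the ratio of all libraries. These values decide neither for nor against that library alone, or maternal tissue content, as a candidate explanation. Whether let-7f widens the variation among placentas remains a hypothesis.

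Other single libraries stood apart within their group: Igf2bp1 in vehicle male 2 at 12.69 (next 12.32) on the log2 scale, Ogt in vehicle female 4 at 12.22 (11.41), Hmga2 in vehicle female 3 at 7.332 (6.476), and the share of reads on Lars2 in vehicle female 4 at 16.06% (0.674%). That share is uncertain as a level of the gene, since reads resembling ribosomal RNA can be assigned to it, which was not tested. In all, 14 such values were found in 135 sets of 1 group and 1 measure, where chance gives about 1 in 20 groups. The let-7f males, with 3 libraries, were too few for this screen and were not in it, so that it says nothing of them. Of the 14, 8 were of let-7f female 6, over lists that are not independent, and whether 14 is more than chance gives was not tested.

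The effect of let-7f differed between the sexes by camera for 10 lists, given here as the median female minus male effect on the log2 scale. Trophoblast giant cell genes were at 0.7615, mitochondrially encoded genes at 0.7034, junctional zone genes at 0.6411 and immediate early genes at 0.4534. Uterine natural killer genes were at -2.513, yolk sac endoderm genes at -2.018, decidua genes at -1.301, glucocorticoid genes at -0.3586, cholesterol synthesis genes at -0.2525 and ribosomal protein genes at -0.208. No list differed with an estimated correlation, where the lowest adjusted p was 0.579, and 59 of 100 splits of the samples called as many lists, with up to 19, so that chance is not excluded for the real count of 10.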

How the results depend on the processing

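Alternatives with DESeq2, edgeR, exact permutation, the 3 covariates together or 2 libraries left out were chosen after seeing the data, and the others before. Of 30604 refits of named genes, 30527 kept their direction and side of the threshold or were not called in either, 17 lost and 60 gained a call, and 0 reversed. Of 3720 refits of lists by camera, 3434 stayed on their side, 140 lost and 134 gained a call, and 12 reversed. A reversal was counted only for genes or lists called in the main fit, and few genes were. Called or not, the sign differed in 387 of the gene refits and 258 of the list refits. In the order mean of both sexes, males, females, difference, vehicle and let-7f sex comparison, DESeq2 called 12, 1, 12, 6, 16 and 4 genes, and on the 2 groups compared alone 19 in males, 11 in females, 425 in vehicle and 5 in let-7f. No filter gave 1 gene in females, array quality weights 14 in vehicle, and 3 covariates together 2 for the mean of both sexes (Igf2 at -1.15, adjusted p = 0.0287, and Gm49394). Estimated correlation and fry called 0, 0, 0, 0, 1 and 1 lists, and exact permutation 0 in all 6, also without vehicle female 4 and let-7f female 6, where the splits within 1 sex or treatment are too few for 1 list alone to pass. The cause was not tested in any of these.

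Leaving out 1 library at a time gave 0 to 0 genes for the mean of both sexes, 0 to 1 in males, 0 to 2 in females, 0 to 1 for the difference, 2 to 5 in vehicle and 2 to 3 in let-7f. Lists called ranged from 9 to 15, 13 to 19, 1 to 12, 8 to 13, 5 to 9 and 9 to 17, and the correlation of male and female effects from -0.0821 to 0.3300. Where the camera test of a called list turned without 1 library, medians ranged for ribosomal protein genes from -0.2971 to 0.0181 in females, 0.0111 to 0.3172 in vehicle, -0.0725 to 0.2326 in males and -0.2251 to 0.0935 in let-7f. They ranged in males from -0.143 to 0.932 for decidua, -0.5231 to -0.0563 for macrophage, -0.4723 to 0.0157 for interferon, -0.5292 to 0.2532 for matrix and -1.3627 to 0.1211 for erythroid genes. In let-7f they ranged from 0.0185 to 1.6068 for erythroid and -0.1265 to 0.5407 for endothelial genes, and for the difference from -0.6098 to 1.4798 for junctional zone genes. Medians that turned while the camera test did not ranged in males from -0.3548 to 0.0325 for giant cell, -0.4203 to 0.0176 for immediate early and -0.0298 to 0.2930 for let-7 target genes, and from -0.2963 to 0.0053 for matrix genes as the mean of both sexes.

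With the replicate number as a block, the pairing was checked first, on 16 same-number pairs that correlated at -0.385 to 0.321. Of these pairs, 5 were over 0.1, and 3 of 18 libraries correlated best with their own number. Pairs within 1 treatment were at 0.184 and -0.061 for vehicle 6 and 7. For let-7f 2, 3 and 4 they were at 0.036, -0.385 and -0.004. With treatment and number as a random block, the correlation within blocks was estimated at 0.0109. The check gave no clear sign of pairing by number. It cannot exclude a shared dam or litter, since most same-number pairs crossed treatments and the labels do not state what a number marks. A fixed block of treatment by number left 3 residual degrees of freedom and called 0 genes in vehicle and 0 in let-7f. Depth limits calls of genes near the limit that 0 reads allow, up to 7.83 normalized counts.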

Other observations

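The counts of splits and the limma and camera tests of this part were planned before the result was seen.

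Imprinted, transporter and chromatin gene lists, given so far by their adjusted p only, had smaller medians than the junctional zone list and were not called. The let-7f against vehicle log2 fold changes, as the mean of both sexes, were 0.40 ± 0.17 for the imprinted splicing gene Snrpn, 0.30 ± 0.14 for the imprinted G protein gene Gnas and -0.38 ± 0.20 for the growth inhibitor gene Grb10, and none passed (limma). Imprinted genes as a list were lower in 20 of 36 members (median -0.15, camera adjusted p = 0.604), and nutrient transporters in 20 of 30 (-0.09, 0.232). Of epigenetic regulators, 13 of 19 were higher (0.13, 0.119), among them the Polycomb gene Ezh2 at 0.44 ± 0.20 and the deacetylase gene Hdac2 at 0.29 ± 0.11. H19, Meg3, Airn and Kcnq1ot1 were not in the table.

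None of the single genes that follow passed over all genes (limma). Female minus male log2 differences among vehicle placentas were 1.22 ± 0.60 for Mt1, 0.94 ± 0.42 for Mt2 and 0.63 ± 0.26 for the cell cycle inhibitor gene Cdkn1a. The let-7f against vehicle log2 fold changes in males were 0.72 ± 0.28 for Cdkn1a and 1.18 ± 0.39 for the glucose transporter gene Slc2a3, and Slc2a3 was at -1.12 ± 0.37 in female against male let-7f placentas.

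Other splits of the same samples were counted beside each result. For the mean of both sexes the real count was 0 genes, with 3 at most in another of 100 splits, so that all 100 gave as many, and 11 lists, with up to 19 elsewhere and 51 of 100 splits as high. In males the real count was 0 genes in all 56 splits, with 0 as the highest of the others. It was 17 lists, reached by 1 of 56 splits (the real one) with up to 16 elsewhere, the only list count that no other split reached. This count met the rule fixed beforehand, that under 0.05 of the splits give as many, but before any adjustment for the number of counts made. Its macrophage and immediate early calls each had a camera adjusted p of 0.0491 and ended in 10 and 14 of 18 refits without 1 library. Since several counts were made and none was adjusted for, chance is not excluded for the male list count. In females the real count was 0 genes (100 of 100 splits as large, up to 2476 elsewhere) and 9 lists (75 of 100, up to 19). For the difference it was 0 genes (100 of 100, up to 2 elsewhere). Among vehicle placentas, 3 genes were called between the sexes, against at most 1 in another split, and 1 of 100 splits gave as many. They included Eif2s3y and Ddx3y, which had served to check the sex labels, so that this count says little beyond Y-linked genes. The other, Gm26992, lost its call in 6 of 18 refits without 1 library. The real count of 7 lists was reached by 50 of 100 splits (up to 15). Among let-7f placentas the real count was 2 genes (6 of 84 splits, up to 955 elsewhere) and 11 lists (64 of 84, up to 21), and chance is not excluded for these counts. The 2 genes themselves, Eif2s3y and Ddx3y, did not overlap between the 8 male and 10 female libraries.

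Few splits gave over 10 genes, 3 of 100 in females and 4 of 84 among let-7f placentas. The 2 that follow were picked as the highest of those run, and whether the samples hold a structure beside the groups compared was not tested. In females, the split with 2476 genes put vehicle female 4 with let-7f female 4, 5 and 6, against all the others. Among let-7f placentas, the split with 955 genes put let-7f male 3 with let-7f female 5 and 6 against the other 6. Let-7f female 6 and let-7f female 5 were on the same side in both.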
